A study of Homo sapiens with 18 samples.

How the data were processed

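RNA was taken from 18 cultures of 3 cancer cell lines (HUH7, DLD1 and NCIH838), with 3 biological replicates of CTRL and 3 of KDSR KO per line, making 6 groups. Lentivirus brought in lentiCRISPR with a non-targeting guide or a KDSR guide, puromycin was given for 5 days, and RNA was taken on day 8 (HUH7, DLD1) or day 10 (NCIH838). The authors deposited TPM values for 27166 genes in all libraries, with gene identifiers, positions and lengths. The submitters' processing notes name featureCounts 2.0.0 and hg38; the aligner is not given in the sources used here, nor is the handling of reads that map to several genes. The deposited TPM summed to 998845 to 999105 per library, slightly under the full total of TPM, because genes with few reads had been left out: the smallest total over the 18 libraries was 10 reads. TPM times gene length gave whole multiples of a step in each library, for 100% of values within 0.01 reads, so the read counts could be recovered and were used for depth and for an added alternative. All 27166 identifiers, names and merged exon lengths matched GENCODE 29 (58780 genes); the start positions also matched, while the end positions differed for 6917 genes, and coordinates were taken from GENCODE 29.

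Depth was 17039634 to 20385767 recovered reads per library. KDSR, on chromosome 18 from 63327726 to 63367510 (hg38, minus strand), had 156 to 306 reads per library in HUH7, 821 to 1529 in DLD1 and 616 to 742 in NCIH838. Library labels were joined to the table's columns through the sample numbers in the descriptions, with 0 value columns left unmapped. Replicates of a group were compared by chi-square over genes with at least 20 reads, and none were identical.

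The comparisons, tests, gene lists and most other settings were chosen before the data were examined. Levels were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options), with 1 mean per group and 12 residual degrees of freedom. Genes entered if their mean over the 6 libraries of at least 1 line was at least 1 TPM (19869 genes), and the p-values of a line were adjusted by Benjamini-Hochberg over genes with a mean of at least 1 TPM in that line. A gene was called at an adjusted p under 0.05. Adding 1 to TPM pulls the log2 changes of genes of low level toward 0. Contrasts were KDSR KO minus CTRL within each line, the average of the 3, the differences between lines in pairs and an F test over the lines. The last 3 kinds were run on the 12558 genes tested in all lines. The KDSR level was also compared by an exact permutation test of TPM, two-sided. Overlaps of calls between lines were tested with Fisher's exact test.

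The 35 gene lists covered sphingolipid metabolism, stress responses, protein quality control, lipid and energy metabolism, growth, signalling, tissue markers and RNA quality. A list was tested with camera (limma, preset correlation 0.01) where at least 5 members were tested, adjusted over the lists of a line, with camera with an estimated correlation and fry beside it. Genes named in the text followed a rule: in each line up to 10 rises and 10 falls, the largest among called genes with a mean of at least 5 TPM over the line's 6 libraries and all 3 KDSR KO libraries on 1 side of the range of CTRL; up to 4 members with the smallest p of each list past camera; any member of both sphingolipid lists; 18 genes fixed in advance; genes called alike in all 3 lines, of which there were 0; and the 10 genes with the smallest p of the F test and a mean of at least 5 TPM. Names of clones, LINC, LOC and MIR genes and pseudogenes of a listed parent were passed over. Not every gene that met the rule is named. Genes named outside this rule are marked as chosen after their values were seen.

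The procedure was tested on simulated data, libraries drawn with 200 genes changed per line. At folds of 1.25, 1.5, 2 and 3, limma called 35.4%, 61.2%, 77.1% and 95.9% of changed genes in HUH7. The shares were 34.0%, 62.0%, 83.7% and 81.8% in DLD1, and 16.3%, 65.3%, 80.4% and 91.8% in NCIH838. Of unchanged genes it called 0.348%, 0.164% and 0.292% in the same order of lines, or 55, 25 and 47 genes. True calls at these folds were 17, 30, 37 and 47 in HUH7. They were 17, 31, 41 and 36 in DLD1, and 8, 32, 37 and 45 in NCIH838. False calls were thus a larger share of the simulated calls than the adjusted p threshold aims at, in each line. Whether this holds for the real libraries was not tested. Other settings fixed in advance were a pseudocount of 0.1, no filter and a filter at 5 TPM, median ratio scaling (genes of at least 10 TPM), quantile normalization, leaving out mitochondrial and rRNA genes, a replicate block, plain eBayes, array weights, a test against a log2 change of 0.5, a fit of each line alone and leaving out each library. Alternatives added after the data were seen were limma voom on recovered reads, HUH7 fitted alone without each library, median ratio scaling without HUH7 CTRL replicate 1, a fit without HUH7 CTRL replicate 1 and NCIH838 KDSR KO replicate 2, and removal of each library's lowess trend with GC content against the mean of its line (span 0.3). Labels were permuted within lines over 100 draws with a fixed seed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 handled the tables, with version 1.17.8 of the data.table package in R, and matplotlib 3.10.9 drew the plots.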

Results

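The data are gene expression values of 18 RNA sequencing libraries from 3 human cancer cell lines: HUH7 from a hepatocellular carcinoma of the liver, DLD1 from the colon and NCIH838 from the lung. In each line, cells carrying lentiCRISPR with a guide against KDSR (KDSR KO) were compared with cells carrying a non-targeting guide (CTRL). There were 3 libraries per group, which the series' design text calls biological triplicates. The stated aim was to compare the mRNA profiles of the lines with and without the knockout. KDSR encodes 3-ketodihydrosphingosine reductase, an enzyme of the endoplasmic reticulum that acts early in the de novo synthesis of sphingolipids, after serine palmitoyltransferase and before the ceramide synthases. Puromycin selection lasted 5 days, and RNA was taken on day 8 after infection in HUH7 and DLD1 and on day 10 in NCIH838. Levels are in TPM, a unit that gives each gene's share of the measured mRNA after correction for gene length. Reads recovered per library ranged from 17039634 (DLD1 CTRL replicate 3) to 20385767 (HUH7 KDSR KO replicate 3).

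KDSR mRNA was lower in the KDSR KO libraries of HUH7 and DLD1, and differed by less than the spread between replicates in NCIH838. In HUH7 it was 5.08, 6.54 and 5.74 TPM in CTRL and 3.67, 4.01 and 3.21 TPM in KDSR KO, a mean 37.2% lower (5.79 ± 0.730 against 3.63 ± 0.401, mean ± SD, n = 3 each; exact permutation p = 0.1, two-sided). In DLD1 it was 29.7, 32.2 and 27.2 TPM in CTRL and 19.5, 19.4 and 18.7 TPM in KDSR KO, a mean 35.2% lower (29.7 ± 2.5 against 19.2 ± 0.413, n = 3 each; exact permutation p = 0.1). In NCIH838 it was 11.9, 13.7 and 14.7 TPM in CTRL and 13.8, 12.5 and 12.3 TPM in the libraries labelled KDSR KO, a mean 4.10% lower (13.4 ± 1.39 against 12.9 ± 0.821, n = 3 each; exact permutation p = 0.7). A p of 0.1 is the smallest that 3 libraries against 3 can give. In limma, the spread of a gene was taken over the 6 groups and drawn toward that of genes of like level. By limma, KDSR fell by 0.60 on the log2 scale in DLD1 (adjusted p = 0.000775), while the log2 changes were -0.55 in HUH7 (adjusted p = 0.114) and -0.05 in NCIH838 (adjusted p = 0.681). The change in NCIH838 differed from that in HUH7 by 0.50 (limma, adjusted p = 0.0105) and from that in DLD1 by 0.55 (adjusted p = 0.0114). A frameshift made by Cas9 need not lower the mRNA, so these levels do not measure the loss of the protein. No reads were available to check the edited site, so the knockout is taken from the labels, and in NCIH838 nothing in these data shows it; KDSR KO below names the labelled group. The HUH7 change passed the limma threshold in 4 of 30 alternative fits. These were median ratio scaling (adjusted p = 0.0366), quantile normalization (0.0435), leaving out mitochondrial and rRNA genes (0.0458) and removal of each library's GC trend (0.00716). It did not pass in the others, among them limma voom and the fits with each library left out.

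**Figure D1:**
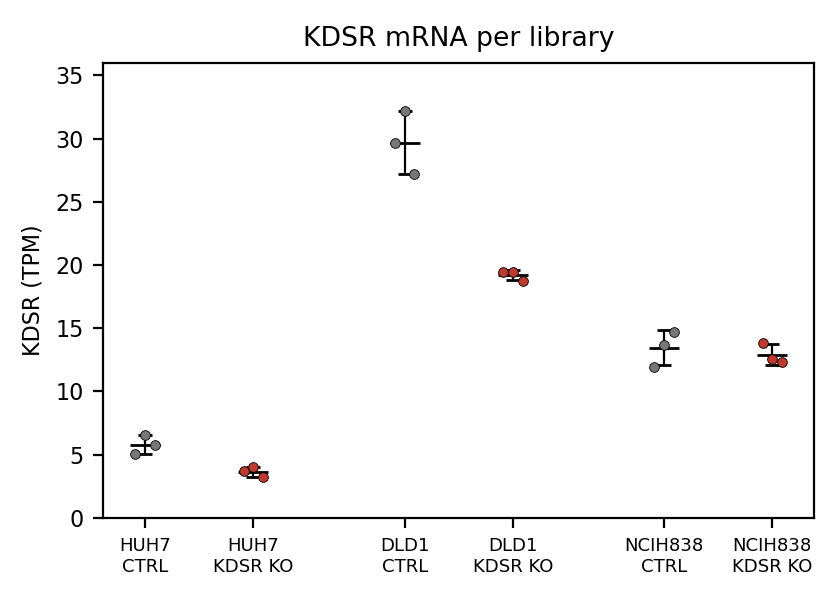
KDSR mRNA in TPM for each library (dots) of the CTRL and KDSR KO groups of HUH7, DLD1 and NCIH838, with the mean and SD of 3 libraries. The KDSR KO libraries lie under all CTRL libraries in HUH7 and DLD1, and overlap them in NCIH838.

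The lines differed in their sphingolipid genes before any knockout. KDSR itself was lowest in HUH7 CTRL (5.79 TPM), intermediate in NCIH838 CTRL (13.4 TPM) and highest in DLD1 CTRL (29.7 TPM). The log2 difference was 2.18 between DLD1 and HUH7 (limma, adjusted p = 5.36e-12), 1.09 between NCIH838 and HUH7 (adjusted p = 3.29e-08) and -1.09 between NCIH838 and DLD1 (adjusted p = 3.34e-08). SPTLC2, a catalytic subunit of serine palmitoyltransferase, followed the same order at 6.03 ± 0.817, 25.8 ± 0.630 and 56.6 ± 1.17 TPM in HUH7, NCIH838 and DLD1 (mean ± SD, n = 3 each). The ceramide synthase CERS2 was highest in HUH7 (316 ± 17.0 TPM, against 88.3 ± 9.44 in DLD1 and 110 ± 9.74 in NCIH838). SGMS2, a sphingomyelin synthase, was at 0.346 TPM in HUH7 and at 31.1 and 37.3 TPM in DLD1 and NCIH838, and SPHK1, a sphingosine kinase, was at 28.6, 0.711 and 17.5 TPM in the same order. Of 53 sphingolipid genes compared between control libraries, 48 differed between DLD1 and HUH7, 44 between NCIH838 and HUH7 and 47 between NCIH838 and DLD1. Of all 19869 genes fitted, 70.6%, 73.0% and 73.0% differed in the same comparisons, so most genes set these lines apart.

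In HUH7, no gene passed the threshold between KDSR KO and CTRL. Chaperone and stress genes that moved far in the other two lines were not called here. HSPA5, the main chaperone of the endoplasmic reticulum, was at 974 ± 80.8 TPM in CTRL and 1057 ± 37 TPM in KDSR KO (n = 3 each). DNAJB1, a cytosolic co-chaperone, was at 230 ± 5.16 and 219 ± 5.84 TPM, and HSPA1B, an inducible HSP70, at 61.9 ± 2.69 and 61.2 ± 4.69 TPM. DDIT3, the stress transcription factor CHOP, was at 29.1 ± 1.56 and 35.4 ± 2.29 TPM. Among sterol genes, TM7SF2 and DHCR7, reductases of cholesterol synthesis, were at 60.4 ± 2.99 and 587 ± 27.6 TPM in CTRL and at 48.0 ± 0.926 and 475 ± 5.52 TPM in KDSR KO. By limma, 0 of 16104 genes had an adjusted p under 0.05, while 1806 had an unadjusted p under 0.05 (819 higher, 987 lower) where 805 would by chance; limma voom on recovered reads also gave 0. The smallest adjusted p was 0.0677, for MINOS1P3, a pseudogene at 3.20 TPM in KDSR KO that was named after its values were seen. In 16.9% of genes all 3 KDSR KO libraries lay on the same side of the range of CTRL, where chance gives 10%.

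Adjusted over the list alone, some members of lists passed in HUH7, against 0 over all genes, among them KDSR in de novo sphingolipid synthesis (lower), CTH and DDIT3 among ATF4 and CHOP targets (higher), STIP1 in the heat shock response (lower), AKR1B10 among NRF2 targets (higher), BIK in apoptosis (higher) and MUC13 among intestinal markers (higher). CTH, STIP1, AKR1B10, BIK and MUC13 were named after their values were seen. Of 34 lists tested, 1 passed camera: cholesterol synthesis was lower (25 members, median log2 change -0.06; adjusted p = 0.0457, and adjusted p = 0.992 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. ATF4 and CHOP targets missed the threshold (median 0.10, adjusted p = 0.0534), and passed as higher with a pseudocount of 0.1 (0.0468), with limma voom (0.047), without KDSR KO replicate 3 (0.0475), without CTRL replicate 1 (0.000561) and after removal of the GC trend (3.12e-08). They did not pass with an estimated correlation (adjusted p = 0.992). The call of cholesterol synthesis was also lost under quantile normalization (adjusted p = 0.0848) and without CTRL replicate 2 (0.167), CTRL replicate 3 (0.206), KDSR KO replicate 1 (0.115) or KDSR KO replicate 2 (0.0588). CTRL replicate 1 stood apart from the other HUH7 controls, with 12.5% of TPM in mitochondrially encoded genes against 7.07% and 8.34%, and without it the count of genes was also 0.

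In DLD1, inducible chaperones were among the largest rises. HSPA6, an HSP70 made under severe stress, rose from 2.57 ± 0.749 to 293 ± 11.7 TPM (114-fold). HSPA1B rose from 138 ± 10.6 to 1446 ± 59.3 TPM (10.5-fold). DNAJB1 and BAG3 rose by less: DNAJB1 rose from 309 ± 16.9 to 996 ± 0.323 TPM (3.22-fold). BAG3, a co-chaperone of HSP70, rose from 335 ± 22.4 to 984 ± 16.2 TPM (2.94-fold; n = 3 each). CRYAB, a small heat shock protein, rose from 0.0214 TPM, close to 0, to 11.1 ± 1.33 TPM. OSGIN1, a growth inhibitor induced by oxidative stress, rose 5.62-fold to 58.7 ± 3.62 TPM, and ZFAND2A, a regulator of the proteasome, rose 4.36-fold to 82.4 ± 4.18 TPM. The 10 largest rises also held genes of other kinds. CYP4F11, a cytochrome P450, rose from 2.25 ± 0.571 to 13.4 ± 1.13 TPM, the chemokine CCL26 from 29.7 ± 6.43 to 130 ± 19.0 TPM, SDCBP2, a scaffold protein, from 2.41 ± 0.0599 to 13.4 ± 0.869 TPM and ANKRD1, a YAP target, from 7.59 ± 0.837 to 34.2 ± 0.447 TPM. Sterol genes were among those that fell. INSIG1, a sterol sensor, fell from 232 ± 12 to 135 ± 6.89 TPM. TM7SF2 fell from 102 ± 6.84 to 58.1 ± 5.00 TPM.

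The heat shock list had the smallest camera p of the 32 lists tested in DLD1. Of its 22 members tested, 18 rose and 0 fell over all genes (19 and 0 adjusted over the list alone; median log2 change 0.45, camera adjusted p = 1.25e-30, and adjusted p = 0.00113 with an estimated correlation). HSPA1A and HSPA1B are near-identical copies, and HSPA6 has a near-identical neighbour, so the division of reads among these genes is uncertain. Of 36 members of the ATF6 and XBP1 arms of the unfolded protein response, 20 rose and 0 fell (24 and 0 adjusted over the list alone; median 0.19, adjusted p = 5.57e-22, and adjusted p = 0.0158 with an estimated correlation). HSPA5 rose from 857 ± 49.6 to 1908 ± 38.1 TPM. HERPUD1, which acts in degradation of misfolded proteins, rose from 57.8 ± 2.52 to 134 ± 6.35 TPM. The chaperone HSP90B1 rose from 1045 ± 55.3 to 1542 ± 8.51 TPM. Of 31 targets of ATF4 and CHOP, 16 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.36, adjusted p = 7.44e-22, and adjusted p = 0.00196 with an estimated correlation). DDIT3 rose 3.72-fold to 90.8 ± 4.80 TPM. ATF3, a stress-induced transcription factor, rose 3.22-fold to 48.1 ± 1.96 TPM. PPP1R15A, which directs dephosphorylation of eIF2alpha, rose 2.52-fold to 205 ± 3.43 TPM; TRIB3, another CHOP target, was at 246 ± 19.4 and 272 ± 12 TPM and did not pass, but did after removal of the GC trend (adjusted p = 0.00197).

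Genes of protein degradation and of the oxidative stress response rose as groups in DLD1. Of 31 proteasome subunits, 19 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.26, camera adjusted p = 1.38e-21, and adjusted p = 0.0221 with an estimated correlation). PSMC4 rose from 237 ± 10.2 to 372 ± 6.27 TPM. PSMC1 rose from 60.3 ± 2.15 to 82.9 ± 2.70 TPM. Of 22 NRF2 targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.37, adjusted p = 2.26e-17, and adjusted p = 0.00113 with an estimated correlation). FTL, the ferritin light chain, rose from 4588 ± 175 to 9367 ± 606 TPM. TXNRD1, a thioredoxin reductase, rose from 267 ± 12.6 to 486 ± 5.27 TPM. AKR1B10, an aldo-keto reductase, rose from 1.68 ± 0.390 to 9.04 ± 0.501 TPM; the member that fell was PGD, of the pentose phosphate pathway, named after its values were seen. SQSTM1, an autophagy receptor and NRF2 target, rose 2.02-fold to 353 ± 8.50 TPM. Of 22 autophagy genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 3.32e-07, and adjusted p = 0.0562 with an estimated correlation).

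Lipid synthesis and Wnt target genes fell in DLD1. Of 25 genes of cholesterol synthesis and its regulation, 20 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.46, camera adjusted p = 8.06e-14, and adjusted p = 0.0383 with an estimated correlation). Lanosterol synthase LSS fell from 98.8 ± 8.91 to 62.8 ± 1.70 TPM. FDPS, of the mevalonate pathway, fell from 171 ± 6.5 to 121 ± 4.89 TPM. Of 15 genes of fatty acid synthesis, 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.29, adjusted p = 0.000176, and adjusted p = 0.105 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell from 1068 ± 40.6 to 754 ± 14.7 TPM. FASN, fatty acid synthase, fell from 661 ± 88.6 to 459 ± 7.26 TPM; the gene that rose was ME1, malic enzyme, which is also an NRF2 target and was named after its values were seen. Of 12 Wnt targets, 9 fell and 0 rose (11 and 0 adjusted over the list alone; median log2 change -0.37, adjusted p = 1.64e-05, and adjusted p = 0.0159 with an estimated correlation). ASCL2, a transcription factor of intestinal stem cells, fell from 442 ± 35.2 to 299 ± 13.7 TPM. LGR5, a receptor for R-spondins, fell from 58.0 ± 0.439 to 46.6 ± 0.922 TPM, a call lost with a pseudocount of 0.1 (adjusted p = 0.0677).

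Replication genes were lower in DLD1 and several immediate early genes were higher. Of 24 genes of S phase, 13 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.23, camera adjusted p = 1.62e-06, and adjusted p = 0.0993 with an estimated correlation). GINS2, part of the replicative helicase complex, fell from 83.6 ± 2.76 to 62.5 ± 2.23 TPM. Of 15 immediate early genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.000114, and adjusted p = 0.105 with an estimated correlation). JUN, a subunit of AP-1, rose 3.09-fold to 127 ± 1.71 TPM. DUSP1, a MAP kinase phosphatase, rose 2.64-fold to 35.5 ± 1.54 TPM, and the transcription factors EGR1 and EGR3, named after their values were seen, fell. Of 14 NF-kB and inflammatory genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.11, adjusted p = 0.000599, and adjusted p = 0.0562 with an estimated correlation). The chemokine CXCL8 rose from 4.93 ± 1.45 to 16.2 ± 1.66 TPM. Of 20 hypoxia and glycolysis genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 1.62e-06, and adjusted p = 0.0562 with an estimated correlation). NDRG1 rose from 14.0 ± 0.103 to 31.7 ± 0.884 TPM. The 13 mitochondrially encoded genes took 8.96%, 6.5% and 6.32% of TPM in CTRL and 8.90%, 8.35% and 9.59% in KDSR KO. None passed over all genes or adjusted over the list alone, although MT-ND4L and MT-ND3 passed over all genes without CTRL replicate 1 (adjusted p = 0.0334 and 0.0409). As a list they were higher (median 0.28, adjusted p = 0.00239, and adjusted p = 0.446 with an estimated correlation), a call also lost under quantile normalization (0.446) and after removal of the GC trend (0.0783).

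Some sphingolipid genes in DLD1 changed, in both directions. Of all genes tested in this line 17.3% were called, so the counts below do not set sphingolipid genes apart. Of 15 genes of de novo synthesis, 3 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.06, camera adjusted p = 0.489). Besides KDSR, the serine palmitoyltransferase subunit SPTLC3 fell from 17.9 ± 0.902 to 12.7 ± 1.3 TPM. Its small subunit SPTSSB fell from 14.7 ± 1.08 to 11.4 ± 1.07 TPM. By limma, the adjusted p of SPTLC3 was 0.013, and 0.0507 without KDSR KO replicate 1 and 0.052 without KDSR KO replicate 2. That of SPTSSB was 0.0263, and 0.0855, 0.0713, 0.053 and 0.115 without CTRL replicate 1, CTRL replicate 2, KDSR KO replicate 1 and KDSR KO replicate 2, 0.0688 with a pseudocount of 0.1 and 0.0624 with a replicate block. SPTLC1 was called higher under median ratio scaling (0.0325), quantile normalization (0.036) and after removal of the GC trend (0.00268). Of 34 genes of sphingolipid turnover and signalling, 6 rose and 1 fell (6 and 1 adjusted over the list alone); the median was -0.05 although camera gave the direction as up (adjusted p = 0.106). PSAP, the precursor of the saposins that help lysosomal sphingolipid breakdown, rose from 488 ± 31.8 to 707 ± 17.1 TPM. The lysosomal alpha-galactosidase GLA rose from 78.6 ± 1.33 to 117 ± 5.25 TPM. SPHK1 rose from 0.711 ± 0.160 to 1.86 ± 0.209 TPM, and CERK, ceramide kinase, fell from 74.2 ± 1.77 to 60.5 ± 1.34 TPM. The other 3 that rose were SAMD8, SPNS2 and ASAH2, and each lost its call without KDSR KO replicate 1, 2 or 3 (adjusted p from 0.0685 to 0.126). SAMD8 also lost it without CTRL replicate 2 (0.0667) or 3 (0.151), SPNS2 without CTRL replicate 1 (0.139) or 2 (0.124), and ASAH2 without CTRL replicate 1 (0.0735) or 3 (0.205). With a pseudocount of 0.1 and with a replicate block the adjusted p-values were 0.0509 and 0.0784 for SAMD8, 0.293 and 0.108 for SPNS2, and 0.0603 and 0.0691 for ASAH2.

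In DLD1, limma called 2674 of 15478 genes (799 higher, 1875 lower), of which 70 rose and 24 fell by more than 1 on the log2 scale. The share called higher was 29.9%, and was 47.5% under median ratio scaling (1139 higher, 1261 lower), 56.0% under quantile normalization (1233, 970), 39.9% without mitochondrial and rRNA genes (1014, 1525) and 59.5% after removal of each library's GC trend (1883, 1282). The count was 67 when the log2 change was tested against 0.5, 4242 with array weights, 1609 without CTRL replicate 3 and 1749 without KDSR KO replicate 3. Among the genes that fell most, RN7SL2, a 7SL RNA with near-identical copies, lost its call without CTRL replicate 1 (adjusted p = 0.0868), CTRL replicate 3 (0.0948), KDSR KO replicate 2 (0.113) or KDSR KO replicate 3 (0.13).

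**Figure D2:**
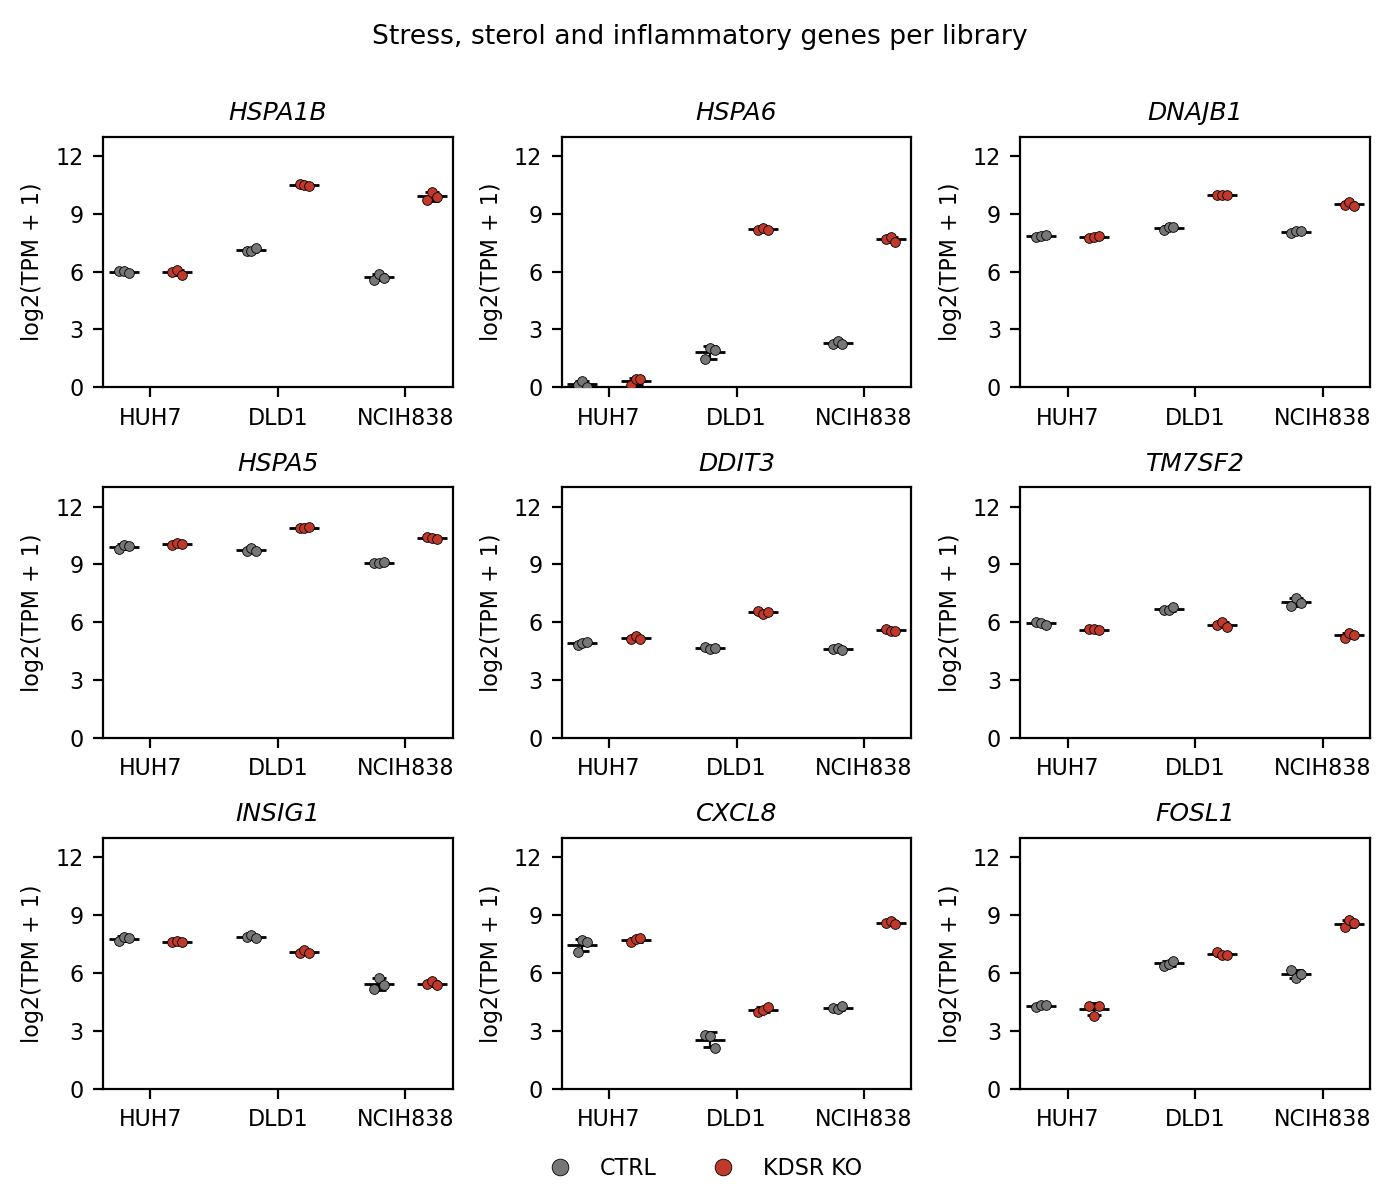
Levels of 9 stress, sterol and inflammatory genes as log2(TPM + 1) for each library (dots; CTRL grey, KDSR KO red) of HUH7, DLD1 and NCIH838, with the mean and SD of 3 libraries. HSPA1B, HSPA6, DNAJB1, HSPA5 and DDIT3 rose in DLD1 and NCIH838 and were not called in HUH7, and CXCL8 and FOSL1 rose by 4.42 and 2.63 on the log2 scale in NCIH838.

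In NCIH838, inducible chaperones and inflammatory genes were among the largest rises. HSPA6 rose from 3.94 ± 0.226 to 203 ± 17.3 TPM (51.5-fold). CXCL8 rose from 17.3 ± 1.14 to 390 ± 21.3 TPM (22.6-fold). HSPA1B rose from 51.3 ± 5.35 to 960 ± 145 TPM (18.7-fold). HSPA1A rose from 158 ± 4.02 to 2794 ± 357 TPM (17.6-fold). FOSL1, a subunit of AP-1, rose from 60.7 ± 9.18 to 379 ± 42.7 TPM (6.24-fold; n = 3 each). SERPINB2, a serine protease inhibitor, rose from 0.641 ± 0.426 to 22.5 ± 3.54 TPM. BCL2A1, an anti-apoptotic NF-kB target, rose from 1.23 ± 0.261 to 18.8 ± 3.25 TPM. The matrix protease MMP3 rose from 1.97 ± 1.01 to 19.1 ± 1.67 TPM, and RHCG, an ammonium transporter, from 2.35 ± 0.596 to 25.1 ± 3.66 TPM. TM7SF2, among the genes that fell furthest, fell from 131 ± 18.5 to 39.1 ± 3.45 TPM. PEG10, an imprinted gene of retrotransposon origin, fell from 274 ± 8.06 to 79.4 ± 13 TPM. DIRAS3, an imprinted small GTPase, fell from 9.49 ± 1.81 to 1.68 ± 0.305 TPM. RNU7-140P, a small pseudogene of few reads, fell by 2.67 on the log2 scale (limma, adjusted p = 0.0202), a call lost without KDSR KO replicate 1 (0.0686), without KDSR KO replicate 2 (0.0734) or with a pseudocount of 0.1 (0.0604).

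Of 19 NF-kB and inflammatory genes in NCIH838, 17 rose and 0 fell (18 and 0 adjusted over the list alone; median 1.2, camera adjusted p = 2.08e-17, and adjusted p = 0.000906 with an estimated correlation). The cytokine IL6 rose from 27.1 ± 1.26 to 156 ± 16.2 TPM. The chemokine CXCL1 rose from 7.87 ± 1.21 to 61.9 ± 5.56 TPM. IER3, an early stress gene, rose from 96.3 ± 7.70 to 375 ± 44.8 TPM. All 14 immediate early genes tested rose (14 adjusted over the list alone; median 1.39, adjusted p = 8.35e-15, and adjusted p = 0.00708 with an estimated correlation). DUSP1 rose from 131 ± 1.39 to 499 ± 74.4 TPM. JUN rose from 26.5 ± 2.72 to 81.6 ± 9.30 TPM. The transcription factor MAFF rose from 12.5 ± 1.48 to 45.6 ± 5.40 TPM. Of 12 targets of ERK signalling, 9 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.68, adjusted p = 5.67e-09, and adjusted p = 0.00708 with an estimated correlation). The ERK phosphatase DUSP6 rose from 4.34 ± 0.223 to 15.1 ± 1.49 TPM. DUSP5, a related phosphatase, rose from 43.6 ± 2.33 to 110 ± 6.87 TPM. The feedback inhibitor SPRY4 rose from 4.10 ± 0.531 to 18.5 ± 0.732 TPM, and the gene that fell was cyclin D1, CCND1.

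Protein quality control genes also rose in NCIH838. Of 36 members of the ATF6 and XBP1 arms, 28 rose and 0 fell (29 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 1.15e-16, and adjusted p = 0.0318 with an estimated correlation). HSPA5 rose from 539 ± 8.32 to 1327 ± 62.6 TPM. SELENOS, of the degradation machinery of the endoplasmic reticulum, rose from 51.8 ± 1.85 to 85.5 ± 1.76 TPM. ERN1, the stress sensor IRE1, rose from 5.95 ± 0.416 to 14.0 ± 0.771 TPM. Of 23 heat shock genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.42, adjusted p = 6.96e-12, and adjusted p = 0.0318 with an estimated correlation). DNAJB1 rose from 267 ± 8.92 to 718 ± 52.3 TPM. The small heat shock protein HSPB8 rose from 56.4 ± 1.40 to 189 ± 10.4 TPM. Of 31 proteasome subunits, 25 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.38, adjusted p = 4.39e-14, and adjusted p = 0.0793 with an estimated correlation). PSMC4 rose from 566 ± 14.9 to 935 ± 46.5 TPM. Of 33 ATF4 and CHOP targets, 16 rose and 9 fell (16 and 10 adjusted over the list alone; median 0.18, adjusted p = 0.000322, and adjusted p = 0.242 with an estimated correlation). PPP1R15A rose 5.20-fold to 231 ± 21.8 TPM. SESN2, a stress-induced inhibitor of mTORC1, rose 3.33-fold to 133 ± 18.8 TPM. DDIT3 rose 2.02-fold to 47.1 ± 1.57 TPM, while the serine synthesis genes PHGDH and PSAT1, named after their values were seen, fell by 0.46 and fell by 0.29 on the log2 scale.

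Genes of lipid and energy metabolism fell in NCIH838, in lists whose calls were lost with an estimated correlation. Of 36 nuclear genes of oxidative phosphorylation, 30 fell and 0 rose (33 and 0 adjusted over the list alone; median -0.32, camera adjusted p = 5.26e-08, and adjusted p = 0.283 with an estimated correlation). SDHA, of succinate dehydrogenase, fell from 75.5 ± 3.03 to 53.4 ± 1.16 TPM. NDUFV1, of complex I, fell from 170 ± 6.76 to 125 ± 8.38 TPM. Of 25 genes of cholesterol synthesis and its regulation, 18 fell and 2 rose (18 and 2 adjusted over the list alone; median -0.41, adjusted p = 0.00131, and adjusted p = 0.328 with an estimated correlation). ACAT2, of the first step, fell from 53.2 ± 1.81 to 28.9 ± 1.44 TPM. FDPS fell from 109 ± 4.66 to 71.8 ± 2.11 TPM. Of 15 genes of fatty acid synthesis, 9 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.30, adjusted p = 0.00225, and adjusted p = 0.305 with an estimated correlation). The desaturase FADS2 fell from 85.9 ± 8.94 to 43.5 ± 3.16 TPM. SCD fell from 563 ± 48.1 to 357 ± 7.03 TPM. CPT1A, which brings fatty acids into mitochondria for oxidation, fell from 116 ± 8.37 to 61.5 ± 1.26 TPM.

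Cell cycle genes fell in NCIH838 as well. Of 24 genes of S phase, 15 fell and 2 rose (15 and 2 adjusted over the list alone; median -0.31, camera adjusted p = 0.001, and adjusted p = 0.305 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, fell from 731 ± 19.9 to 502 ± 37.4 TPM. MCM3 fell from 197 ± 4.30 to 141 ± 4.39 TPM; the 2 that rose, CCNE1 and RRM2, were named after their values were seen. Of 22 genes of G2 and M phase, 14 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.27, adjusted p = 0.00105, and adjusted p = 0.305 with an estimated correlation). CCNB2, cyclin B2, fell from 132 ± 3.12 to 92.0 ± 10.9 TPM. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 59.0 ± 1.98 to 147 ± 14.6 TPM, while of 22 p53 targets 6 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.216). Of 25 NRF2 targets, 8 rose and 6 fell (8 and 7 adjusted over the list alone; median 0.06, adjusted p = 0.216), and HMOX1, heme oxygenase, rose from 53.2 ± 1.77 to 103 ± 5.70 TPM.

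Some sphingolipid genes in NCIH838 changed, in both directions. Of all genes tested in this line 42.5% were called, so the counts below do not set sphingolipid genes apart. Of 14 genes of de novo synthesis, 1 rose and 4 fell (1 and 4 adjusted over the list alone; median -0.05, camera adjusted p = 0.664). These counts depended on the scaling: 2 rose and 3 fell under median ratio scaling, 3 and 3 under quantile normalization, and 6 and 3 after removal of the GC trend. SPTLC1 (adjusted p = 0.000184), SPTLC2 (0.000686), ORMDL1 (0.00665), CERS2 (0.00571) and CERS6 (0.0403) were called higher after removal of the GC trend, and CERS2 also under median ratio scaling (0.0258). SPTSSA, a small subunit of serine palmitoyltransferase, fell from 191 ± 12.4 to 90.0 ± 13.5 TPM. SPTLC3 fell from 3.28 ± 0.534 to 1.21 ± 0.233 TPM. The dihydroceramide desaturase DEGS1 fell from 263 ± 9.96 to 216 ± 22.5 TPM (limma, adjusted p = 0.0187, and 0.0633 without CTRL replicate 1 and 0.0929 without KDSR KO replicate 2). The ceramide synthase CERS5 fell from 15.0 ± 1.10 to 12.6 ± 1.40 TPM (adjusted p = 0.0324). The adjusted p of CERS5 was 0.138, 0.0557 and 0.162 without CTRL replicate 3, KDSR KO replicate 2 and KDSR KO replicate 3, 0.0618 with a replicate block, 0.0699 under median ratio scaling, 0.139 under quantile normalization and 0.0924 after removal of the GC trend. ELOVL1, which makes very long fatty acids, rose from 124 ± 3.37 to 139 ± 6.94 TPM (adjusted p = 0.0138, and 0.0567 without CTRL replicate 3 and 0.0629 without KDSR KO replicate 1). Of 35 genes of turnover and signalling, 8 rose and 5 fell (8 and 5 adjusted over the list alone; median 0.04, adjusted p = 0.146), against 10 and 5 under median ratio scaling, 11 and 5 under quantile normalization, and 15 and 5 after removal of the GC trend. UGCG, glucosylceramide synthase, and SGPL1, sphingosine-1-phosphate lyase, were called higher under median ratio scaling (adjusted p = 0.0215 and 0.00234), by limma voom (0.0386 and 0.0357) and after removal of the GC trend (0.000166 and 0.000295). SPHK1 rose from 17.5 ± 0.616 to 41.1 ± 3.15 TPM. Of the 8 rises and 5 falls, the call of S1PR3 was lost with a pseudocount of 0.1 (0.131), with a replicate block (0.0716) and without CTRL replicate 1 (0.127), CTRL replicate 2 (0.0802), KDSR KO replicate 1 (0.109) or KDSR KO replicate 3 (0.0859). That of SPHK2 was lost without CTRL replicate 2 (0.0576) or KDSR KO replicate 2 (0.0895), that of PSAP without CTRL replicate 1 (0.0613) or KDSR KO replicate 2 (0.0685), that of PLPP2 with a pseudocount of 0.1 (0.0611) and that of PLPP1 without CTRL replicate 2 (0.0502). Acid ceramidase ASAH1 fell from 17.2 ± 0.837 to 10.6 ± 1.11 TPM. The sphingosine-1-phosphate receptor S1PR5 fell from 20.6 ± 2.17 to 12.1 ± 0.889 TPM.

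In NCIH838, limma called 6945 of 16347 genes (2560 higher, 4385 lower), of which 348 rose and 183 fell by more than 1 on the log2 scale. The share called higher was 36.9%, and was 47.3% under quantile normalization (3319 higher, 3691 lower) and 51.8% after removal of each library's GC trend (4088, 3803). The count was 644 when the log2 change was tested against 0.5, and NCIH838 was collected on another day than the other two lines. KDSR KO replicate 2 stood apart from the other KDSR KO libraries of this line, and without it the count was 6146 (6987 without it and HUH7 CTRL replicate 1).

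**Figure D3:**
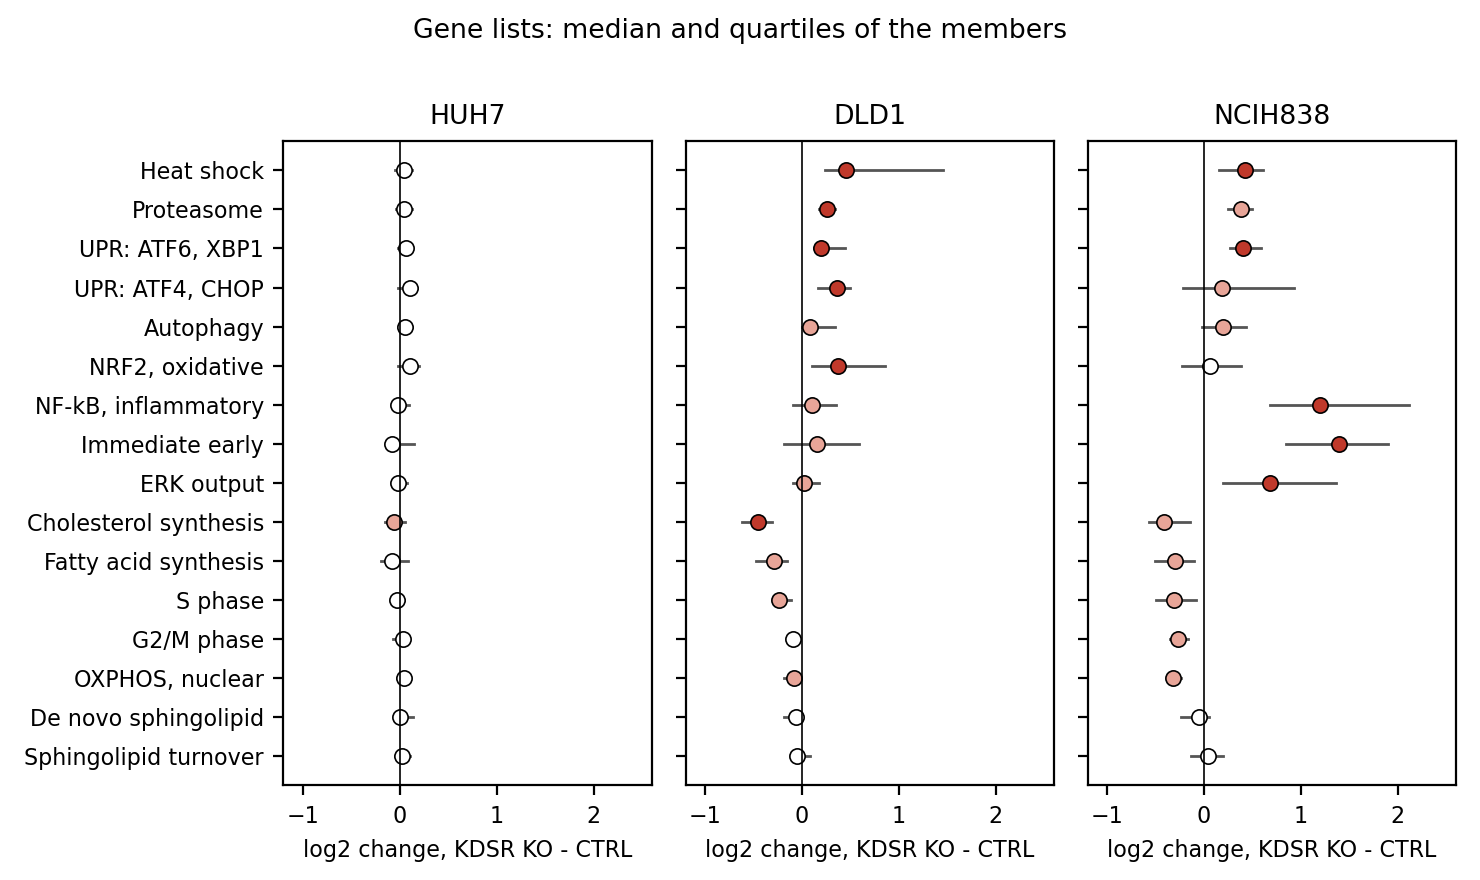
Median (dot) and quartiles (line) of the log2 changes, KDSR KO minus CTRL, of the members of 16 gene lists in HUH7, DLD1 and NCIH838. Dark red dots passed camera with a preset and an estimated correlation, pale red dots only with the preset one and white dots with neither; the heat shock list passed both in DLD1 (median 0.45) and NCIH838 (0.42) and neither in HUH7.

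DLD1 and NCIH838 shared more changed genes than independent lists would. Of 13467 genes tested in both, 509 rose in both, where 114.5 would by chance (odds ratio 16.0, Fisher's exact p = 6.26e-255), and 986 fell in both, where 454.8 would (odds ratio 5.01, p = 5.04e-192). In opposite directions, 36 rose in DLD1 and fell in NCIH838, and 88 did the reverse. Genes are not independent units, so these p-values do not measure how the overlap would repeat in other cultures. The median change of all tested genes was below 0 in both lines (-0.07 and -0.09), and the overlap was not counted under another scaling. HSPA5, DNAJB1, BAG3, DDIT3, PSMC4 and SQSTM1 rose in both, and TM7SF2, FDPS, SCD and MCM3 fell in both. Across 12558 genes tested in all 3 lines, which are not independent replicates, the log2 changes of DLD1 and NCIH838 had a Pearson correlation of 0.36 and a Spearman correlation of 0.36. The values were 0.15 and 0.29 for HUH7 and DLD1, and -0.06 and -0.09 for HUH7 and NCIH838. With each library left out in turn, the Pearson correlations of these pairs ranged from 0.0556 to 0.183 and from -0.110 to 0.00995. By limma, 0 genes were called with the same sign in all 3 lines, since 0 were called in HUH7 (limma voom: 0 in HUH7). At an unadjusted p under 0.05 in each line, 52 were higher, 238 lower and 114 of mixed sign. The average change over the lines passed for 4497 genes (1505 higher, 2992 lower; 33.5% higher, and 43.6% under median ratio scaling, 47.9% under quantile normalization and 53.2% after removal of the GC trend).

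**Figure D4:**
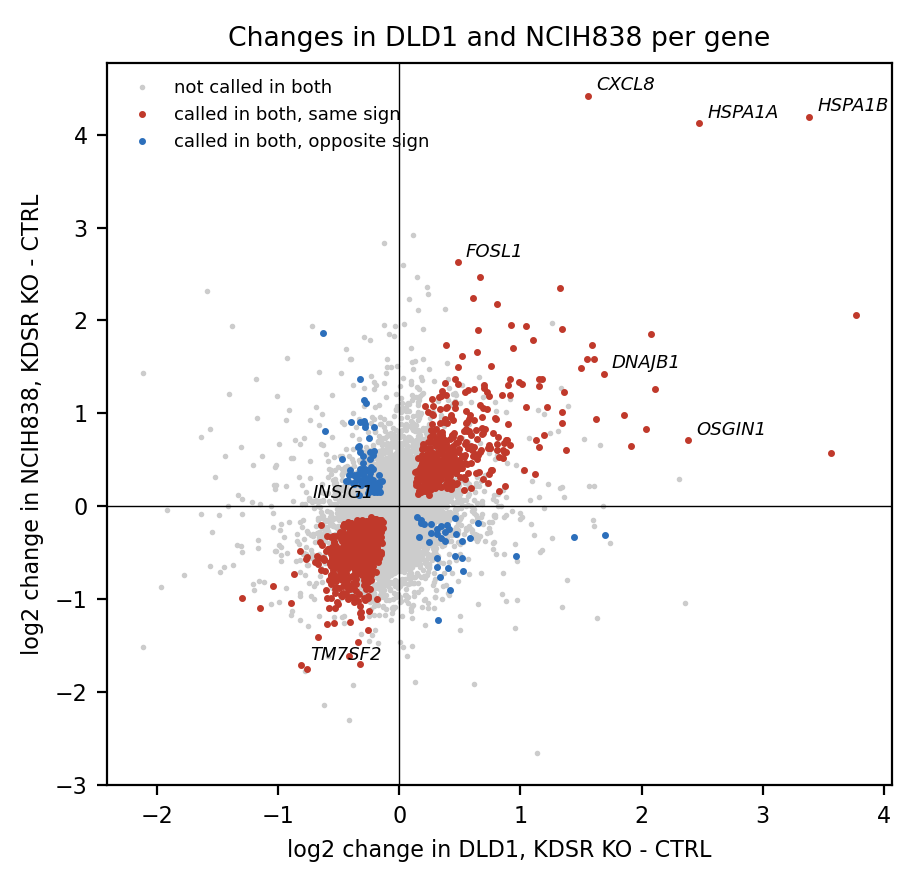
Log2 changes, KDSR KO minus CTRL, in DLD1 and NCIH838 for the 12558 genes tested in all 3 lines, with a Pearson correlation of 0.36. Red points were called in both lines with the same sign, blue points with opposite signs and grey points were not called in both.

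The change with KDSR KO differed between lines for chaperone, inflammatory and signalling genes. By the limma F test, 3886 of 12558 genes differed between the 3 lines. HSPA1B changed by -0.02, 3.38 and 4.19 on the log2 scale in HUH7, DLD1 and NCIH838 (adjusted p = 2.94e-10), and DNAJB1 by -0.06, 1.69 and 1.42 (adjusted p = 1.57e-09). BAG3 changed by -0.17, 1.55 and 1.58 (adjusted p = 1.17e-08). HES1, a target of Notch, changed by -0.06, -0.32 and 1.37 (adjusted p = 1.07e-09), and SPRY4 by -0.08, -0.04 and 1.94 (adjusted p = 4.62e-09). MARC1, a mitochondrial amidoxime reductase, changed by -0.06, -0.33 and -1.70 (adjusted p = 1.17e-08) and NDRG1 by -0.04, 1.12 and 0.35 (adjusted p = 1.31e-08). In pairs, 350 genes differed between DLD1 and HUH7 (219 with a difference above 0), 4237 between NCIH838 and HUH7 (1528 above 0) and 2259 between NCIH838 and DLD1 (1183 above 0). The heat shock list differed between DLD1 and HUH7 (median difference 0.39, camera adjusted p = 1.91e-35, and adjusted p = 0.00098 with an estimated correlation). The change of NRF2 targets was lower in NCIH838 than in DLD1 (median difference -0.40, adjusted p = 7.93e-09, and adjusted p = 0.0121 with an estimated correlation). NF-kB and inflammatory genes rose further in NCIH838 than in DLD1 (median difference 1.22, adjusted p = 5.29e-17, and adjusted p = 0.00127 with an estimated correlation) and than in HUH7 (1.66, adjusted p = 7.32e-17, and adjusted p = 0.00132 with an estimated correlation). No line was collected on both days, so the line and the day of collection cannot be told apart in comparisons with NCIH838, and a single KDSR guide was used in all lines.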

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

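Of the tests in this part, the bound set on the HUH7 count without CTRL replicate 1 (a setting itself fixed in advance), the comparison of depth, the search for DLD1 changes in HUH7, the test for blood cells and the removal of GC trends were chosen only after the result was seen. Limma voom was also added after the data were seen.

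The effect of KDSR KO differed between lines by a test of the difference itself, for 3886 of 12558 genes over the 3 lines, 350 between DLD1 and HUH7, 4237 between NCIH838 and HUH7 and 2259 between NCIH838 and DLD1 (limma). Among the genes singled out by the F test were HSPA1B (adjusted p = 2.94e-10), HES1 (1.07e-09), DNAJB1 (1.57e-09), HSPA1A (1.86e-09), SPRY4 (4.62e-09), BAG3 (1.17e-08), MARC1 (1.17e-08), ZFAND2A (1.17e-08) and NDRG1 (1.31e-08). In 100 draws of relabelled libraries, the real one included, the average over lines, 4497 genes, was reached by 1 (highest other 2305). At that number of draws, this argues against chance for a change in at least 1 line. It does not show a change shared by all 3 lines, since 0 genes were called in HUH7. The 3886 genes of the F test were also reached by 1 of 100 (highest other 2854), as were the 350 (228) and the 4237 (3437), and the 2259 by 4 (3270). A draw that keeps 1 line's labels intact still holds that line's change, a structure of the samples that the high counts of other draws point to. The draws are then no test of a difference between lines, and for these 4 counts they leave chance open.

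The lists below passed camera for a difference between lines, with a preset and with an estimated correlation. Camera compares the members with all other genes, so the median differences given beside them are descriptions. Between DLD1 and HUH7 the lists were ATF4 and CHOP targets (median difference 0.24), ATF6 and XBP1 targets (0.21), heat shock (0.39), proteasome (0.21), NRF2 targets (0.31), hypoxia and glycolysis (0.16) and immediate early genes (0.43). Between NCIH838 and HUH7 they were NF-kB and inflammatory genes (1.66), immediate early genes (1.39) and ERK targets (0.82). Between NCIH838 and DLD1 they were NRF2 targets (-0.40), NF-kB and inflammatory genes (1.22), immediate early genes (0.77) and ERK targets (0.69).

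The first pattern weighed is that 0 genes were called in HUH7 by limma (1806 at an unadjusted p under 0.05; 0 by limma voom). Without CTRL replicate 1, the control library that stood apart, the count was also 0. That fit had 1 control library fewer, and so less power. More lists passed camera in it, none of them with an estimated correlation. The count therefore does not settle whether that library hid small changes. Depth is argued against, since the HUH7 library with the fewest reads had 19423417 and the DLD1 one 17039634 (19.4 M and 17.0 M). A larger spread is argued against only for the libraries without CTRL replicate 1. There the median SD within groups was 0.800 times that of DLD1, and the count was 0 in a fit of less power. With that library, as in the fit reported, the ratio was 1.29. The comparison of spread thus depends on it, and for the fit reported a larger spread stays open. It stays open whether the DLD1 changes recur in HUH7 at a smaller size: of genes called in DLD1, 66.3% of 709 risen genes were above 0 and 73.9% of 1631 fallen genes were below 0 in HUH7, where 55.7% and 44.3% of all genes tested in both lines were. The slope of the HUH7 on the DLD1 changes was 0.116 (0.0773 without CTRL replicate 1), reached by 1 of 10 splits of the HUH7 libraries. The camera p-values with a preset correlation were 0.00512 and 5.57e-17, but the larger of the camera p-values with an estimated correlation was 0.413 (0.0295 for the fallen genes, and 0.113 for them without CTRL replicate 1). Less complete loss of KDSR in HUH7, or less need for the enzyme in a line where its control level was lowest, was not tested. A count of 0 is reached by all 10 splits of the 6 HUH7 libraries by construction (highest other 7), so they say nothing about it, and 6 of the 10 gave at least the 1 list found (highest other 6); 3 libraries against 3 cannot give a share under 0.05.

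The next pattern is the larger rise of inflammatory genes in NCIH838 than in DLD1. RNA from blood cells is argued against, since PTPRC, which encodes the common leukocyte antigen CD45, was at most 0.0198 TPM in the NCIH838 KDSR KO libraries. CD14, a marker of monocytes named after its values were seen, was higher in this line than in the others but at 22.1 TPM in CTRL and 21.8 TPM in KDSR KO. KDSR KO replicate 2, which stood apart, is argued against as the cause, since without it the median difference was 1.12 against 1.22 with it. The later collection of NCIH838 stays open and cannot be told apart from the line, since 0 lines were collected on both days. A biological difference between the lines is also open, and KDSR mRNA was only 4.10% lower in the NCIH838 libraries labelled KDSR KO.

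The last pattern is that more genes were called lower than higher. In DLD1, the genes called higher took 7.15% of TPM in CTRL and 10.5% in KDSR KO, which forces a log2 change of -0.0530 on all others, against a median of -0.07; in NCIH838 the shares were 17.8% and 24.8%, the forced change -0.129 and the median -0.09. These genes were picked because they rose and TPM sum to a fixed total, so the values cannot decide between a shift of shares and a wider fall, and this stays open in both lines. Gene length is argued against, since at most 31.97% of calls were higher in each tertile of genes by length in DLD1 and at most 37.2% in NCIH838. GC content may contribute in DLD1, where 66.1% of calls were higher in the tertile of lowest GC and 15.8% in the tertile of highest GC. In NCIH838 the shares ran the other way, with 26.8% in the tertile of lowest GC, 39.9% in the middle one and 42.6% in the highest. The excess of lower calls was there in every tertile, which argues against GC content alone, while a part played by it stays open. After removal of the GC trend the share called higher was 59.5% in DLD1 and 51.8% in NCIH838. That removal also centres the changes (medians -0.00755 and 0.00234), which by itself evens the directions, so these shares decide nothing about GC.

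Within DLD1 the real split gave 2674 genes, reached by 1 of 10 splits (highest other 5), and 21 lists, reached by 1 of 10 (highest other 16). Within NCIH838 it gave 6945 genes, reached by 1 of 10 (highest other 5), and 20 lists, reached by 1 of 10 (highest other 15). Between control libraries it gave 48, 44 and 47 sphingolipid genes, each reached by 1 of 10 (highest other 0). With 10 splits no share under 0.05 is possible. The count of genes changed alike in all 3 lines, 0, is reached by 100 of 100 draws by construction (highest other 0), so the draws say nothing about it.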

How the results depend on the processing

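Of the settings below, limma voom, fitting HUH7 alone without each library, median ratio scaling without HUH7 CTRL replicate 1, leaving out both HUH7 CTRL replicate 1 and NCIH838 KDSR KO replicate 2, and removing GC trends were chosen only after the data were seen; wherever a value moved, the cause was not tested. The count in HUH7, 0 by limma (1806 at an unadjusted p under 0.05; 0 by voom), was 9 with no filter, 2 under median ratio scaling, 2 under quantile normalization, 5 without mitochondrial and rRNA genes, 1 with a replicate block, 7 with plain eBayes, 4 after GC removal, 4 under median ratio scaling without HUH7 CTRL replicate 1, and 0 to 8 when each library was left out (6 without CTRL replicate 2, 8 without CTRL replicate 3, 3 without KDSR KO replicate 1, 2 without KDSR KO replicate 2). The count alike in all 3 lines, 0, was 1 with no filter, 1 without mitochondrial and rRNA genes, 1 with plain eBayes, 1 after GC removal, and 0 to 2 when each library was left out (2 without HUH7 CTRL replicate 3). AKR1B10, named after its values were seen, was the gene called in all 3 lines where the count was 1. The DLD1 count, 2674, was 4242 with array weights, 67 when tested against a log2 change of 0.5, and 1609 to 3286 when each library was left out (1609 without CTRL replicate 3, 1749 without KDSR KO replicate 3). The NCIH838 count, 6945, was 644 when tested against 0.5; its other values, and all values of the F test and of the average over lines, stayed within 1.5 times. With a replicate block, a test for which the labels give no ground, the blocked counts were 1 in HUH7, 2242 in DLD1, 6723 in NCIH838, 3482 for the F test and 4351 for the average; residuals of libraries with the same number correlated over 0.1 in 1 of 9 cases (-0.05 to 0.13).

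Correlations of changes across genes between HUH7 and DLD1, HUH7 and NCIH838, and DLD1 and NCIH838 were 0.0597 (first pair) and 0.236 (last pair) with a pseudocount of 0.1, and 0.312, -0.0938 and 0.484 with a filter at 5 TPM. Leaving out each library gave 0.0556 to 0.183, -0.110 to 0.00995 and 0.308 to 0.395; the middle one turned positive, at 0.00995, without NCIH838 KDSR KO replicate 2, and was -0.01 without HUH7 CTRL replicate 1. HUH7 and DLD1 fell to 0.0556 without DLD1 CTRL replicate 3 and to 0.0910 without HUH7 CTRL replicate 1.

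No gene changed sign among the calls that voom (2339 in DLD1, 6616 in NCIH838), median ratio scaling (2028, 6331), quantile normalization (1751, 6206) or GC removal (1773, 6311) shared with the fit reported. The same libraries enter each fit, so a gene called in both could hardly change sign, and this says little about how firm the calls are. Many calls were not shared. Of 2674 calls in DLD1 and 6945 in NCIH838, a fit of the line alone kept 1957 and 5604. No named gene reversed with a pseudocount of 0.1, median ratio scaling, a replicate block, voom, GC removal or each library left out. Left-out libraries ended a call in 43 of 954 cases in DLD1 and 18 of 922 in NCIH838. A case is a named gene with a library left out, also where the gene had no call to lose. These are therefore not rates of loss among calls. Median ratio scaling ended the list calls of ribosomal proteins in DLD1 (adjusted p = 0.107) and NCIH838 (0.109) and of ribosome biogenesis in DLD1 (0.0509). After GC removal, ATF4 and CHOP targets (3.12e-08), ribosome biogenesis (0.00121), NRF2 targets (0.00774), p53 targets (0.035) and fatty acid synthesis (0.0392) passed camera in HUH7 with the preset correlation. Camera with an estimated correlation was not run after GC removal, and in the fit reported it gave each of these lists an adjusted p of 0.992. At this depth 77.1% of simulated 2-fold changes were called in HUH7 and 35.4% at the smallest fold drawn, so small changes are often missed. In the same simulation, false calls were a larger share of calls than the adjusted p threshold aims at, in each line.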

Other observations

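Of the tests in this part, only the removal of GC trends was chosen after its result was seen.

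Further gene groups moved in NCIH838. Of 23 genes of TGF-beta, YAP and matrix biology, 11 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.0182, and adjusted p = 0.349 with an estimated correlation and 0.0538 after removal of the GC trend), with CTGF, a matricellular YAP target, from 113 ± 10.0 to 320 ± 19.6 TPM, and TGFB2, a TGF-beta ligand, from 8.93 ± 0.432 to 3.53 ± 0.179 TPM (mean ± SD, n = 3 each). Of 26 apoptosis genes, 10 rose and 7 fell (13 and 7 adjusted over the list alone; adjusted p = 0.00539, and adjusted p = 0.305 with an estimated correlation), with CASP4, an inflammatory caspase, from 19.7 ± 1.08 to 60.5 ± 2.27 TPM and MCL1, an anti-apoptotic protein, from 207 ± 6.04 to 410 ± 16.1 TPM. Of 22 autophagy genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.000421, and adjusted p = 0.28 with an estimated correlation), with SQSTM1 from 148 ± 3.70 to 371 ± 35.1 TPM. MYC rose from 36 ± 0.353 to 80.6 ± 3.65 TPM in NCIH838 and fell from 348 ± 35.1 to 284 ± 4.15 TPM in DLD1. Of 49 ribosomal protein genes in NCIH838, 21 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.14, adjusted p = 0.0229, and adjusted p = 0.603 with an estimated correlation; 0.109 under median ratio scaling, 0.148 after removal of the GC trend, and 0.0811, 0.0823 and 0.155 without CTRL replicate 2, CTRL replicate 3 and KDSR KO replicate 3).

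Markers of the tissue of origin were read in the control libraries. The median level of the hepatocyte list was 635 TPM in HUH7, 0.05 TPM in DLD1 and 0.20 TPM in NCIH838, with ALB, albumin, at 5963 TPM and AFP, alpha-fetoprotein, at 5189 TPM in HUH7 (both named after their values were seen). That of the intestinal list was 30.2 TPM in DLD1, 1.05 TPM in HUH7 and 0.00869 TPM in NCIH838. Its member VIL1 alone was higher in HUH7 (111 TPM) than in DLD1 (16.1 TPM), and was named after its values were seen. The lung list had 7 of its 9 genes in the table and a median of 0.0726 TPM in NCIH838, 0.432 TPM in DLD1 and 0.0247 TPM in HUH7, so its median did not mark NCIH838. Its member KRT7, named after its values were seen, was at 38.6 TPM in NCIH838, 2.76 TPM in DLD1 and 0.387 TPM in HUH7. The other members were under 1 TPM in NCIH838. The blood, endothelium and stroma list had a median of 1.31 TPM in HUH7, 0.0289 TPM in DLD1 and 0.802 TPM in NCIH838. Its members LUM and COL1A1, named after their values were seen, were at 441 and 33.1 TPM in HUH7. Of the RNA quality list, 8 of 12 genes were in the table, and it did not pass camera in HUH7 (adjusted p = 0.259), DLD1 (0.106) or NCIH838 (0.177); it passed camera in DLD1 without CTRL replicate 1 (0.0302) and fry in NCIH838 (0.0172).

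Some libraries stood apart from their group. By chi-square per degree of freedom, HUH7 CTRL replicate 1 differed from replicates 2 and 3 by 19.4 and 17.6, and these from each other by 3.5. NCIH838 KDSR KO replicate 2 differed from replicates 1 and 3 by 14.6 and 9, and these from each other by 5.95. DLD1 CTRL replicate 3 differed from replicates 1 and 2 by 9.40 and 7.25, and these from each other by 3.27. Without HUH7 CTRL replicate 1, 6 lists passed camera in HUH7: mitochondrially encoded genes (higher, median 0.34, adjusted p = 6.89e-06), ATF4 and CHOP targets (higher, 0.000561), cholesterol synthesis (lower, 0.000561), lysosome (lower, 0.0139), intestinal markers (higher, 0.0139) and S phase (lower, 0.0475). None of the 6 passed with an estimated correlation, and the library left out had the highest mitochondrial share of the HUH7 controls.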
